A study of Drosophila melanogaster
Mus musculus with 21 samples.

How the data were processed

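Nuclear RNA was measured in 21 libraries of 7 groups, 3 per group, from mouse embryonic stem cells with Drosophila cells added as a spike-in. Per the labels' protocols, ribosomal RNA was depleted and directional libraries were read as paired ends of 80 bp (PRC1deg) or 40 bp (PRC2deg), with another version of the library kit for each line. Bowtie2, STAR, SAMtools, bedtools and DESeq2 with the mm10 and dm6 builds are named in the submitters' processing notes, and their versions are not given in the sources used here. The authors deposited 5 tables of 20633 entries, 1 per comparison with untreated cells of the same line.

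The log2 fold changes are the authors' own and were deposited without standard errors. They lie near 0 for entries with few reads, as shrunken estimates do: at 2 h of auxin the interquartile range of entries with under 10 untreated reads was -0.0086 to 0.052. The p-value columns deposited by the authors hold adjusted values only. The same 676 entries had no fold change in the 4 auxin tables. The third column, headed as a mean RPKM in untreated cells, was treated as a signal deposited by the authors: its low values multiplied by length gather at 0.119, 0.233 and 0.470 normalised reads in PRC1deg and 0.277, 0.335 and 0.425 in PRC2deg, as a mean of size-factor-normalised reads per kilobase over 3 libraries does. Untreated reads below are that value times the length divided by 1000. The 2 lines were normalised separately by the authors, so levels were not compared between them.

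The planned z statistics needed standard errors, which the tables do not hold, so the authors' deposited values were used as they stand. An entry was called where the adjusted p was under 0.05 and the fold change over 1.5 in either direction. Lists of genes were fixed before the data were examined. For each of 26 lists, 1 entry per symbol was taken, the one with the most untreated reads. Lists with 5 or more measured members were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the log2 fold change, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over all lists and comparisons. A test with an estimated correlation was not possible without values per library. List medians were set against 10000 random lists matched on untreated reads in 20 bins. An upper limit of each p was worked back from the adjusted values to adjust over a list alone. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 did the rest.

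On simulated normal z values for 18724 symbols, some of them shifted, the upper limit held for 100% of p. With the 2 h fold changes shuffled within bins of untreated reads, 100% of random lists of 30 shifted by 0.5 log2 were recovered. The limit holds by construction, and 32.5% of p were recovered exactly. Without a shift, 6% of lists had a cameraPR p under 0.05. The shift was added in full to every member, also those with few reads, and shuffling takes out correlation between genes. These rates of recovery and of false calls therefore need not hold for the real lists. Named genes were, per comparison, the 10 highest and 5 lowest among calls with 50 or more untreated reads, up to 4 members per list by smallest p, the 10 with the smallest p at 2 h among genes higher at all times, and a fixed set of Polycomb and pluripotency genes. Not every gene that this rule names is reported here. Several transcripts of 1 gene count as separate entries. Symbols were those in the tables, and no mouse coordinates were used here. Alternatives were other thresholds, a minimum of 50 reads, centring on the median, counting symbols once, and, for lists, a correlation of 0.05, ranks, genes with 50 or more reads, and a signed z from the upper limit of p.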

Results

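Nuclear RNA was sequenced from mouse embryonic stem cells of 2 engineered lines. In the PRC1deg line, Ring1 (RING1A) was deleted and its paralogue RING1B, the other catalytic subunit of Polycomb repressive complex 1, carried a degron that auxin acts on. In the PRC2deg line, SUZ12, a core subunit of Polycomb repressive complex 2, carried a dTAG degron. The PRC1deg cells were left untreated or given 500 µM auxin for 2, 4, 8 or 24 h, and the PRC2deg cells were left untreated or given 100 nM dTAG-13 for 2 h. Each of the 7 groups had 3 libraries from separate biological replicates, 21 libraries in all, and Drosophila SG4 cells were mixed in before extraction as a spike-in. The values used here are the authors' fold changes and adjusted p-values, which come with no standard error and no value per library. The untreated means add up to 30450536 normalised reads over the 20633 entries of the PRC1deg tables and 29474239 over those of the PRC2deg table, and the depth of single libraries is unknown.

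The degron acts on protein, so transcript levels of the targeted genes do not check the depletion. Rnf2, which encodes RING1B, had log2 fold changes of 0.38 at 2 h, 0.94 at 4 h, 0.74 at 8 h and 0.34 at 24 h in the authors' deposited table, of which those at 4 and 8 h were called higher. Ring1 stayed between 0.00 and 0.43 in the authors' deposited table and was not called at any time. Among the other Polycomb genes, the authors' deposited table gave Cbx2 values of 0.51, 0.77, 1.00 and 0.75 at 2, 4, 8 and 24 h, and Suz12 values of 0.18, 0.53, 0.43 and 0.14. Ezh2, the catalytic subunit of PRC2, reached 0.72 and Eed 0.71 at 4 h in the authors' deposited table, and both were called higher at that time. Pcgf2 had values of 0.24, 0.29, 0.59 and 0.13 in the authors' deposited table. After subtraction of the median of entries with 50 or more untreated reads, the Rnf2, Ezh2, Eed and Cbx2 changes no longer passed 1.5-fold.

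The first comparison asked which genes changed within 2 h of auxin. Among calls with 50 or more untreated reads, Lmx1b, a homeobox factor of limb and midbrain development, had the highest log2 fold change at 3.64, Meis2 3.07 and the tumour suppressor and kidney regulator Wt1 2.67 in the authors' deposited table. Vwc2 (3.38), Gad1 (2.84), an enzyme of GABA synthesis, Shisa6 (2.80), and N-cadherin gene Cdh2 (2.75) were also among the highest in the authors' deposited table. Hs3st3b1 (2.71), St6gal2 (2.63) and Pcdh17 (2.61) completed the highest 10 of these calls in the authors' deposited table. In total 1044 entries were higher and 48 lower, so that 95.6% of calls were higher. Among entries with 50 or more untreated reads, whatever their p, 585 lay over 1.5-fold above their median and 160 over 1.5-fold below it. Chac1, a glutathione-degrading enzyme of the amino acid response, had the lowest value among calls with 50 or more untreated reads at -2.59, followed by Stc1 at -2.08, A230009B12Rik at -1.98, Cacna2d4 at -1.63 and Arhgef6 at -1.39 in the authors' deposited table.

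Of the 39 measured Hox cluster genes, which pattern the body axis, 22 were higher, 0 lower and 17 not past the test at 2 h, and 24 were higher when adjusted over the list alone. Their median log2 fold change was 1.69, above all 10000 random lists matched on untreated reads (cameraPR of limma, adjusted p = 4.3e-61). Hoxd11 had a log2 fold change of 5.87, Hoxa11 5.29, Hoxd13 3.68 and Hoxa10 3.36 in the authors' deposited table. The median Hox member had 4.70 untreated reads, so single fold changes rest on few reads. Of 84 other homeobox genes, 60 were higher, 0 lower and 24 not past the test (62 higher when adjusted over the list alone), with a median of 2.27 (cameraPR, adjusted p = 5.1e-168). Otx1 stood at 3.51 and En1 at 3.06 in the authors' deposited table. Of 49 Pax, Sox, Fox, Tbx, Gata and Zic factors, 31 were higher and 0 lower, also 31 when adjusted over the list alone, and Zic1 (3.85), Tbx18 (3.79), Pax7 (3.39) and Pax6 (2.57) were among them in the authors' deposited table.

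Lineage lists also held calls at 2 h. Of 33 neural genes 9 were higher (11 when adjusted over the list alone), among them Olig2 (4.08), Pou3f2 (3.91), Pou3f3 (3.16) and Ntrk3 (1.94) in the authors' deposited table. Of 25 mesoderm and primitive streak genes 12 were higher (14 when adjusted over the list alone), with Bmp2 at 3.42, Fst at 2.60 and Wnt5a at 2.38 in the authors' deposited table. Of 22 endoderm genes 7 were higher (9 when adjusted over the list alone), with Foxa2 at 2.98 and Gata6 at 2.03 in the authors' deposited table. Of 16 trophoblast genes 6 were higher, also 6 when adjusted over the list alone, with Gata3 at 2.86, Tfap2a at 2.14 and Eomes at 2.06 in the authors' deposited table. Of 17 formative and primed epiblast genes 7 were higher (8 when adjusted over the list alone), including Fgf5 at 1.90 and Zic2 at 1.44 in the authors' deposited table. The median of entries with 50 or more untreated reads lay at 0.15 at 2 h, and with fold changes centred on it 1027 entries were higher. With entries of 50 or more untreated reads only, readjusted, 522 were higher.

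The next comparison was made at 4 h of auxin. Among calls with 50 or more untreated reads, Shisa6 had a log2 fold change of 4.73, Vwc2 4.20, Nfia 4.07, Pax3, a neural crest regulator, 3.92 and Npas3 3.87 in the authors' deposited table. The calcium channel gene Cacna1c (3.79), Trank1 (3.72) and Lmx1b (3.60) followed in the authors' deposited table. In all 2841 entries were higher and 23 lower. Whatever their p, 924 entries with 50 or more untreated reads lay over 1.5-fold above the median of such entries and 406 over 1.5-fold below it. The lowest with 50 or more untreated reads were Chac1 (-1.90), Cacna2d4 (-1.56), Sbsn (-1.50), Nupr1 (-1.36) and Ndufa4l2 (-1.30) in the authors' deposited table. Hox cluster genes had 34 of 39 members higher and a median of 3.08 (35 adjusted over the list alone), and other homeobox genes 71 of 84 with a median of 3.14 (76 adjusted over the list alone). Of 68 Wnt, Fgf, Bmp, Notch and Hedgehog ligands and receptors 43 were higher and 0 lower (45 adjusted over the list alone, 35 with centring), with Fgf9 at 5.02, Wnt5a at 3.73 and Fgf13 at 3.38 in the authors' deposited table. Of 52 axon guidance and ion channel genes 29 were higher and 0 lower (32 adjusted over the list alone), with Kcna1 at 4.73, Efna5 at 3.50 and Unc5c at 3.34 in the authors' deposited table. The median of entries with 50 or more untreated reads was 0.40 at this time, and 1731 entries were higher with fold changes centred on it.

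At 8 h the number of calls was 4430 higher and 15 lower. Among calls with 50 or more untreated reads, Shisa6 (4.32), Trank1 (4.16), Npas3 (4.16), Lmx1b (4.02), Pax3 (4.01), Cacna1c (3.96), Nfia (3.90) and Vwc2 (3.77) were highest in the authors' deposited table. Slc7a11, the cystine transporter, had the lowest value of these at -1.47, then Chac1 at -1.40, Cacna2d4 at -1.24, Rfx8 at -1.23 and Nupr1 at -1.20 in the authors' deposited table. The median of entries with 50 or more untreated reads was 0.50, a fold of 1.41, and 96.7% of them lay above 0. With fold changes centred on that median, 1839 entries were higher. The lower calls stayed at 15 because the adjusted p still tests the change before centring, and whatever their p, 964 entries with 50 or more untreated reads lay over 1.5-fold above the median and 270 over 1.5-fold below it. Of 47 ribosomal protein genes 11 were called higher as deposited, 0 with centring, and 0 when adjusted over the list alone, with a list median of 0.57 (cameraPR, adjusted p = 0.98, and 0.014 by ranks, higher). Of 17 housekeeping genes 3 were higher as deposited and 0 with centring, also 3 when adjusted over the list alone.

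**Figure D1:**
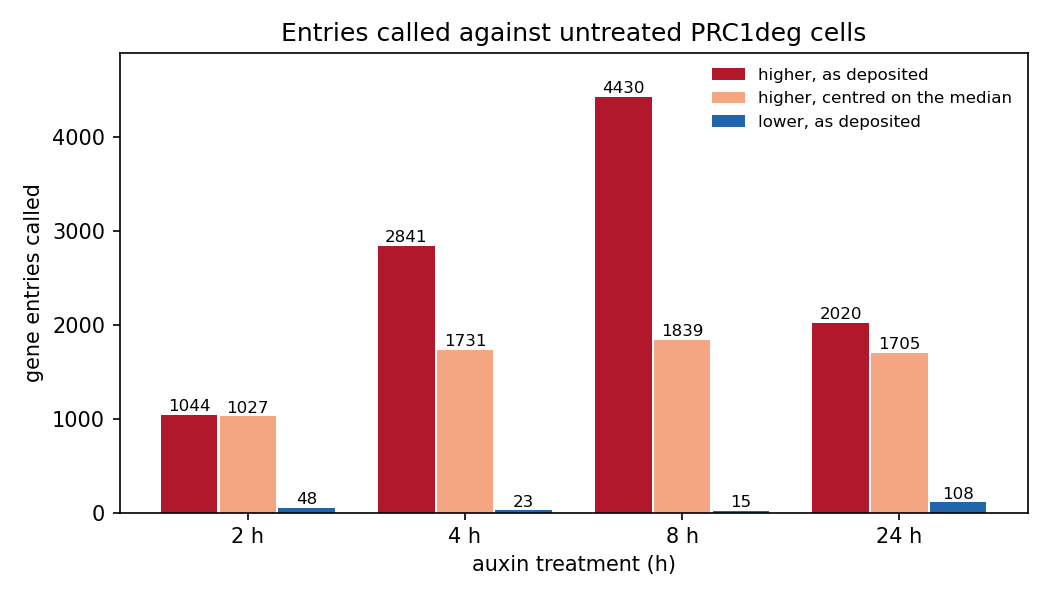
Bars give the number of gene entries (vertical axis) called at each auxin time (horizontal axis, h), as deposited or with fold changes centred on the median of entries with 50 or more untreated reads. Higher calls reach 4430 at 8 h as deposited and 1839 with centring, and lower calls lie between 15 and 108.

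At 24 h Gata6, a regulator of primitive endoderm, was highest among calls with 50 or more untreated reads, with a log2 fold change of 4.16, ahead of Lmx1b (3.91), Pax3 (3.90), the imprinted growth factor gene Igf2 (3.77), Trank1 (3.70), Grb10 (3.70) and Nfia (3.44) in the authors' deposited table. There were 2020 entries higher and 108 lower. Whatever their p, 922 entries with 50 or more untreated reads lay over 1.5-fold above the median of such entries and 436 over 1.5-fold below it. The lowest with 50 or more untreated reads were 6330410L21Rik (-2.50), Chac1 (-2.41), Slc7a11 (-2.33), Cacna2d4 (-2.18) and Fam196b (-2.14) in the authors' deposited table. Hox cluster genes had 34 of 39 members higher with a median of 3.21 (35 adjusted over the list alone). Of 22 endoderm genes 9 were higher and 1 lower (10 and 1 adjusted over the list alone), with Pdgfra at 2.07, Col4a1 at 1.84 and Col4a2 at 1.72 in the authors' deposited table. Of 30 imprinted genes 7 were higher (9 adjusted over the list alone), with Dlk1 at 2.93 and Sfmbt2 at 2.03 in the authors' deposited table, and the list passed cameraPR at an adjusted p of 0.012 but not with a correlation of 0.05, adjusted p = 0.099, or by ranks, adjusted p = 0.19. The median of entries with 50 or more untreated reads was 0.24, and 1705 entries were higher with centring. With entries of 50 or more untreated reads only, readjusted, 1122 were higher. The labels number the 24 h libraries apart from those of 0 to 8 h, and any effect of a separate run cannot be told apart from the time.

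**Figure D2:**
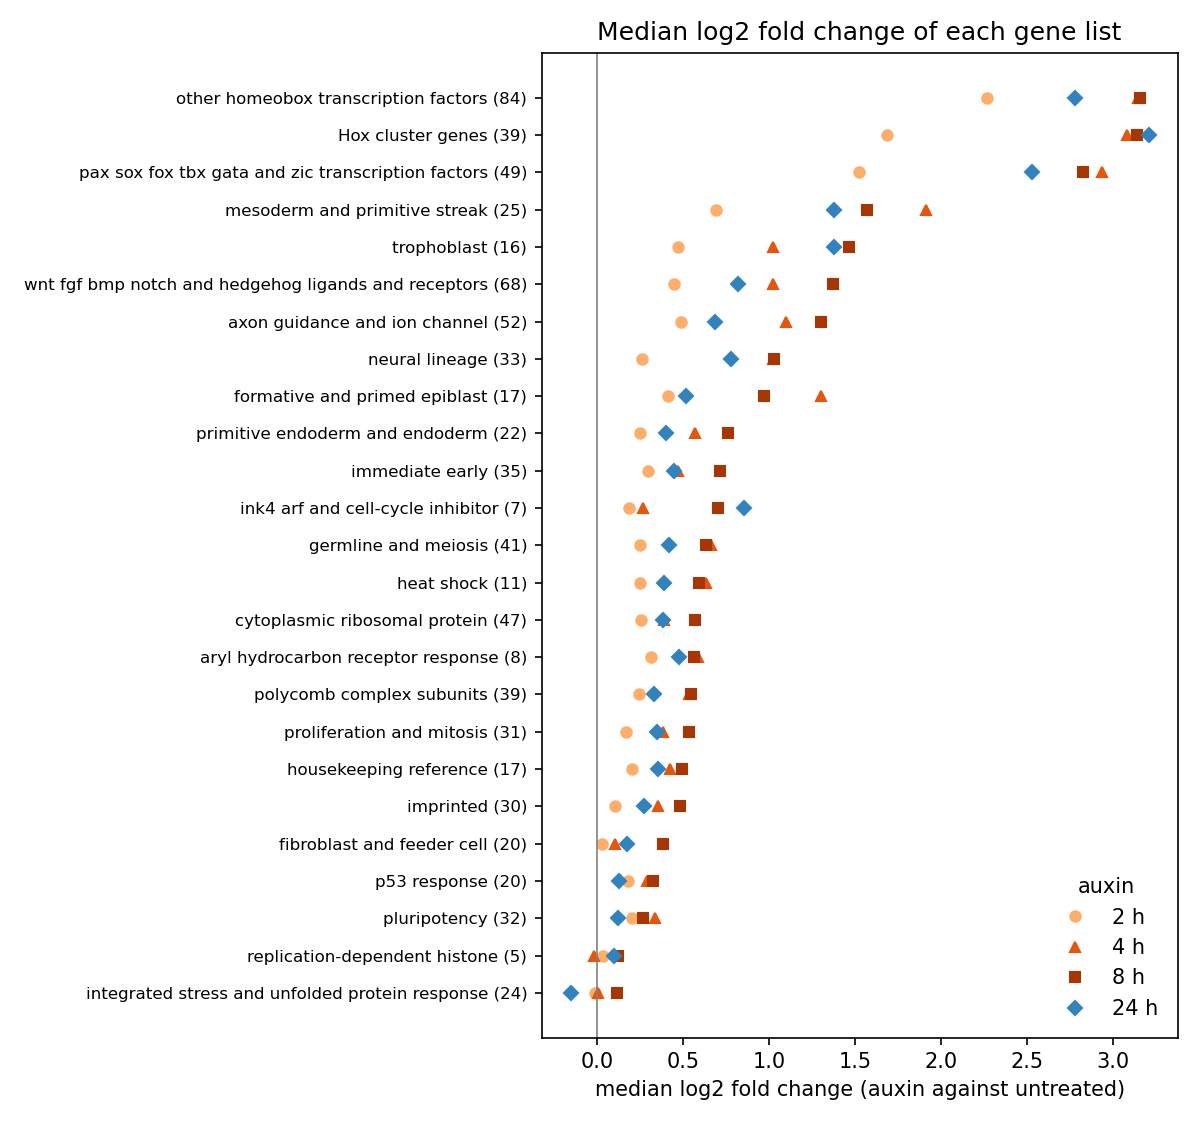
Each row is a gene list with the number of measured members, and each point the median log2 fold change (horizontal axis) against untreated PRC1deg cells at 1 auxin time. Hox cluster genes lie at 1.69 at 2 h and 3.21 at 24 h, and the stress response list at -0.16 at 24 h.

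Few pluripotency genes were called. Of 32 measured members 1, 5, 3 and 1 were higher at 2, 4, 8 and 24 h and 0 were lower, and adjusted over the list alone 1, 5, 2 and 1 were higher, and with centring 1 at each time. Pou5f1 had log2 fold changes of 0.20, 0.15, 0.44 and 0.23, Nanog 0.24, 0.41, 0.11 and 0.24, and Sox2 0.15, 0.25, -0.20 and -0.19 in the authors' deposited table, none of them called. Gbx2 was higher at each time, with values of 1.46, 2.11, 1.60 and 0.96 in the authors' deposited table. Relative to the median of entries with 50 or more untreated reads, the list median was 0.05 at 2 h, -0.06 at 4 h, -0.23 at 8 h and -0.12 at 24 h, where at 4 h the list median of 0.33 lay above the 0.32 of all entries. Among random lists matched on untreated reads, the list median had a percentile of 93.3 at 2 h, 1.1 at 4 h, 0 at 8 h and 2.5 at 24 h. The list did not pass cameraPR with all genes (adjusted p = 0.22 at 8 and at 24 h), but at 8 h it was lower than other genes among those with 50 or more reads (adjusted p = 0.013) and with the signed z (adjusted p = 0.033), and at 2 h it was higher by ranks (adjusted p = 0.0026).

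The stress response list, of amino acid response and unfolded protein response genes, went in both directions. Of 24 members 0, 3, 5 and 3 were higher and 3, 4, 3 and 6 lower at 2, 4, 8 and 24 h, and adjusted over the list alone 0, 3, 6 and 3 were higher and 5, 4, 3 and 7 lower. With centring, 0, 1, 2 and 1 were higher. The amino acid response genes Ddit3 (-1.25) and Trib3 (-1.14) were lower at 2 h, while the chaperone gene Hspa5 was higher at 1.20 and Xbp1 at 1.15 at 8 h in the authors' deposited table. The list median was -0.40 relative to the median of entries with 50 or more untreated reads at 24 h (cameraPR, adjusted p = 0.00028). The call at 8 h was lost with a correlation of 0.05, adjusted p = 0.080.

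Among 39 Polycomb subunit genes 5, 14, 15 and 9 were higher at 2, 4, 8 and 24 h (5, 17, 18 and 9 adjusted over the list alone, and 5, 6, 7 and 6 with centring), and 1 was lower at 24 h. Bmi1 had values of 1.60, 2.81, 2.82 and 2.59, and Cbx8 1.99, 2.80, 2.94 and 2.91 in the authors' deposited table. The list passed cameraPR at 4 and 8 h (adjusted p = 0.044) and not with a correlation of 0.05 (adjusted p = 0.24) or with members of 50 or more reads (adjusted p = 0.10 and 0.14). Of 35 immediate early genes 10, 12, 20 and 8 were higher (11, 14, 21 and 13 adjusted over the list alone, and 10, 9, 10 and 6 with centring), with Egr3 at 3.52 and Nr4a3 at 2.93 at 2 h in the authors' deposited table. That list passed cameraPR at 2 h and at 8 h (adjusted p = 0.0045), the latter not with a correlation of 0.05, adjusted p = 0.070, or with members of 50 or more reads, adjusted p = 0.32. Of 7 cell-cycle inhibitor genes 2, 3, 3 and 4 were higher (2, 3, 4 and 4 adjusted over the list alone), with Cdkn2c at 2.01 at 2 h and 2.63 at 24 h in the authors' deposited table. It passed cameraPR at 24 h (adjusted p = 0.046) and not with a correlation of 0.05, adjusted p = 0.088, with members of 50 or more reads, adjusted p = 0.11, or by ranks, adjusted p = 0.077.

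**Figure D3:**
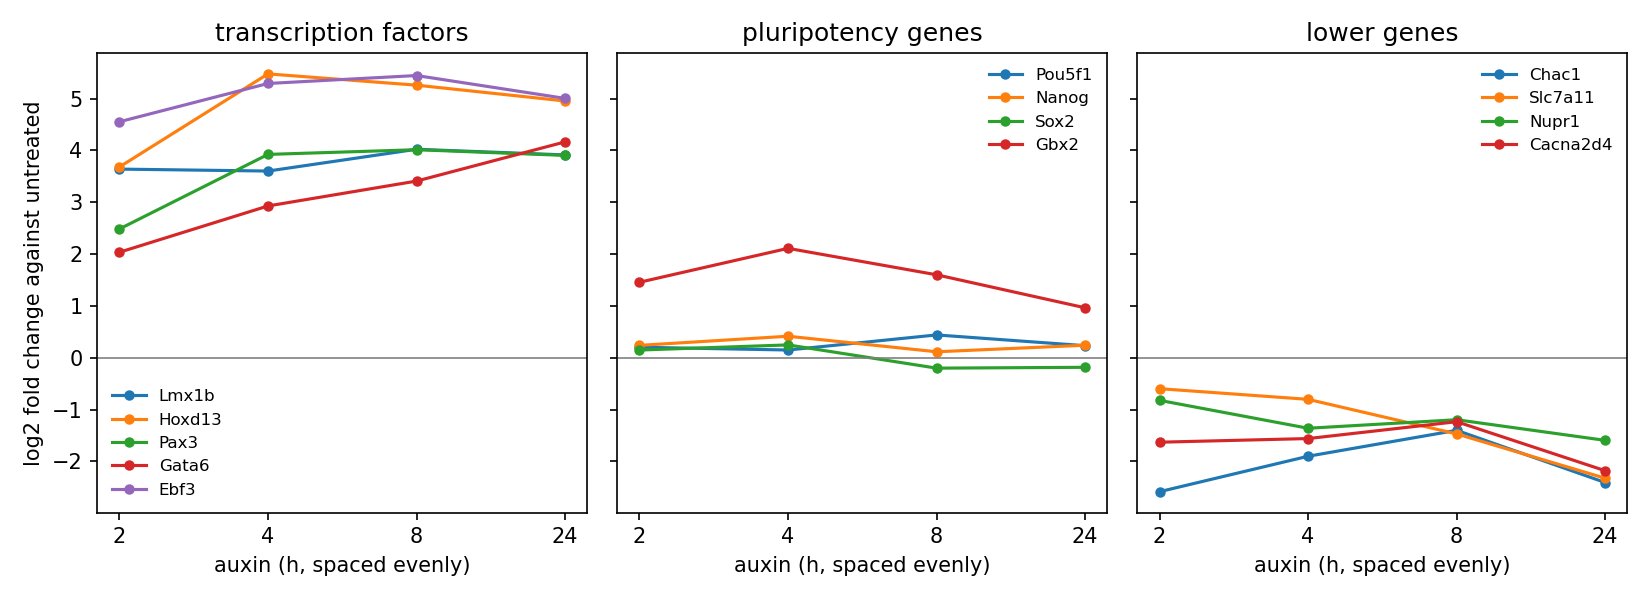
Lines join the log2 fold changes (vertical axis) of single genes at 2, 4, 8 and 24 h of auxin (horizontal axis, spaced evenly), without error bars because the tables hold no standard errors. Lmx1b lies at 3.64 at 2 h and 3.91 at 24 h, and Chac1 at -2.59 and -2.41.

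The higher calls at 2 h were largely found again later. Of the 48 entries lower at 2 h, 14 were lower at 4 h, 5 at 8 h and 17 at 24 h. Only 23 entries were lower at 4 h and 15 at 8 h in all, which limits how many could recur. For lower calls, unchanged groups against shared controls gave at most 7 shared entries for 2 and 4 h in 100 simulated draws. They gave at most 6 for 2 and 8 h and at most 12 for 2 and 24 h. Of the 1044 entries higher at 2 h, 1019 were higher at 4 h, 1004 at 8 h and 901 at 24 h, and 893 were higher at all 4 times. For 2 and 24 h, independent lists would share 119.6 entries, and unchanged groups against shared controls gave a mean of 423.2 in 100 simulated draws. Part of the excess may come from the shared untreated libraries, which could not be split. Ebf3 had the smallest p at 2 h among entries higher at all times, with values of 4.55, 5.29, 5.44 and 5.00 in the authors' deposited table. Nr2f2 (4.56), Elfn1 (3.00), Wnt7b (3.58), Hoxd13 (3.68), Fgf9 (4.69) and Skor1 (5.69) at 2 h were others in the authors' deposited table. The median log2 fold change of the 1044 entries was 1.51 at 2 h, 2.20 at 4 h, 2.23 at 8 h and 1.83 at 24 h. Of 1822 entries first called higher at 4 h, 662 were called higher at 24 h, and of 2017 first called at 8 h, 332 were. With centring, 759 of the former passed at 4 h and 560 at 24 h, and 192 of the latter at 8 h and 179 at 24 h. Chac1, Cacna2d4, Slc6a9, Zc3h6 and A230009B12Rik were lower at all 4 times, a set of 5 named after its values were seen.

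The PRC2deg line was compared before and after 2 h of dTAG-13. No gene was called, with 0 entries higher and 0 lower by the authors' DESeq2 values. Every fold change in the authors' deposited table lay within 0.000985 of 0 on the log2 scale, and the adjusted p took 3 values from 0.999956 to 0.99998. These adjusted values allow at most 975 of 19506 entries an unadjusted p under 0.05. Hox cluster genes had 0 of 39 members called, also 0 when adjusted over the list alone. No list passed cameraPR on the log2 fold change itself. By ranks of the fold change, 4 lists passed cameraPR, all lower than other genes. These were ribosomal protein (adjusted p = 2.6e-06), proliferation (0.0044), immediate early (0.015) and trophoblast genes (0.034). With the signed z, which holds little but the sign where the adjusted p takes 3 values, Hox cluster genes were higher than other genes (adjusted p = 0.019). Their members were positive in 28 cases and negative in 11. Other lists leaned the other way: 40 of 47 ribosomal protein, 25 of 31 proliferation, 26 of 35 immediate early and 13 of 16 trophoblast genes were negative. A shared sign was thus not particular to Hox cluster genes. The fold changes were shrunken nearly to 0, so their sizes cannot be set beside those of the PRC1deg line, and the difference between the lines at 2 h was not tested.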

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

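All tests of differences between auxin times were chosen after the data were seen. The difference of the log2 fold changes at a pair of times was tested per list with cameraPR, which compares a list with other genes and leaves out the error between libraries. The other genes were not matched on reads. Hox cluster, other homeobox, and Pax, Sox, Fox, Tbx, Gata and Zic lists had medians of only 4.70, 5.06 and 12.7 untreated reads. Fold changes of such entries are shrunken, and a difference in shrinkage between times cannot be told apart from a change. Of 100 tests, 26 passed, 17 with a higher and 9 with a lower later value than other genes.

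From 2 to 4 h, the median change of Hox cluster genes was 1.40, of Pax, Sox, Fox, Tbx, Gata and Zic factors 0.82, of other homeobox genes 0.79, of neural genes 0.58, of formative and primed epiblast genes 0.46, of mesoderm genes 0.41, of axon guidance and ion channel genes 0.39, of germline genes 0.39 and of Wnt, Fgf, Bmp, Notch and Hedgehog genes 0.31, against 0.21 for all genes. From 4 to 8 h, immediate early genes moved by 0.16, formative genes by -0.028, aryl hydrocarbon receptor response genes by -0.12 and pluripotency genes by -0.14, against 0.06 for all genes.

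From 8 to 24 h, the median change was -0.44 for axon guidance and ion channel genes, -0.43 for formative genes, -0.43 for Wnt, Fgf, Bmp, Notch and Hedgehog genes, -0.35 for immediate early genes and -0.28 for other homeobox genes, against -0.22 for all genes. From 2 to 24 h, Hox cluster genes moved by 1.31, Pax, Sox, Fox, Tbx, Gata and Zic factors by 0.67, other homeobox genes by 0.66, mesoderm genes by 0.33, neural genes by 0.24, imprinted genes by 0.16, trophoblast genes by 0.14 and pluripotency genes by -0.11.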

How the results depend on the processing

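For counts of calls, the alternatives with a minimum of 50 reads, with centring and with symbols counted once, and for lists the signed z, were chosen after seeing the data, since the planned forms needed standard errors or p-values. No paired analysis was possible because the tables hold no values per library, and for the same reason leaving out replicates, other splits of the samples, other count models and adjustment without filtering were not run. Tests of single genes between times or lines were not run for lack of standard errors. Removing the fold threshold or counting symbols once moved no count by over 1.5 times. At an adjusted p under 0.01, higher calls were 1709 at 4 h and 2267 at 8 h, and lower calls 18, 8, 5 and 55 at 2, 4, 8 and 24 h. With a fold threshold of 2, higher calls were 1702 at 4 h and 2009 at 8 h, and lower calls 22, 11 and 8 at 2, 4 and 8 h. With 50 or more reads, higher calls were 522, 1843 and 1122 at 2, 4 and 24 h. Centring gave 1731 at 4 h and 1839 at 8 h, by its own construction. The global median over all entries was 0.11, 0.32, 0.44 and 0.19 at 2, 4, 8 and 24 h, and 0.17, 0.42, 0.49 and 0.23 with 500 or more reads. Lists lower by ranks numbered 2 at 4 h and 2 at 8 h. At 8 h, lower lists numbered 0 with a correlation of 0.05, 2 with members of 50 or more reads and 2 with the signed z. In the PRC2deg table, 4 lists were lower by ranks, and with the signed z 1 was higher, Hox cluster genes, and 2 were lower. The causes were not tested. Of the fold changes of genes that the naming rule gives, with list members counted where called, 377 kept their side of the threshold with centring and 48 no longer passed it. The lowest untreated values, read as 1 read in 1 library, imply size factors of 2.80, 1.43 and 0.71 for the untreated PRC1deg libraries and 1.20, 1.00 and 0.78 for those of PRC2deg, which mix depth with the share of spike-in, so depth per library is unknown, and small changes of genes with few reads could not be detected.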

Other observations

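The tests of the stress response list, of the sign against expression level, of the sign over symbols and lists, and of length at 24 h were chosen after the result was seen. Other fixed lists also held calls. Among all entries with an adjusted p, 1044 of 18798 were higher at 2 h and 2841 of 17639 at 4 h. At 8 h 4430 of 17253 were higher, and at 24 h 2020 of 17639, so counts within a list are read beside these. Of 8 aryl hydrocarbon receptor response genes 2, 2, 3 and 3 were higher at 2, 4, 8 and 24 h (2, 4, 4 and 3 adjusted over the list alone), with the cytochrome genes Cyp1a1 at 2.34 and Cyp1b1 at 2.69 at 2 h in the authors' deposited table. That list passed cameraPR at 2 h (adjusted p = 0.0013) and 4 h (adjusted p = 0.0080), but not with its 5 members of 50 or more reads (adjusted p = 0.74 and 0.98), and by ranks not at 4 h (adjusted p = 0.058). Of 41 germline genes 3, 16, 19 and 13 were higher (4, 21, 20 and 13 adjusted over the list alone, and 3, 12, 10 and 12 with centring), among them Tdrd1 at 1.94 and Ddx4 at 1.62 at 24 h in the authors' deposited table. The germline list did not pass cameraPR with all genes (adjusted p = 0.11 at 4 h) or with a correlation of 0.05. It was higher with members of 50 or more reads at 4 h (adjusted p = 0.0042) and 24 h (0.0016), with the signed z at 4 h (0.042) and 24 h (0.044), and by ranks at 2, 4, 8 and 24 h (0.028, 0.0024, 0.024 and 0.015). Of 31 proliferation genes 1, 4, 6 and 4 were higher (1, 6, 6 and 4 adjusted over the list alone, and 1, 2, 2 and 1 with centring), and the cyclin gene Ccnd2 stood at 3.00 at 8 h in the authors' deposited table.

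Of 20 p53 response genes 1, 2, 2 and 2 were higher (1, 1, 2 and 2 adjusted over the list alone, and 1, 1, 1 and 2 with centring), with Perp at 1.33 at 4 h in the authors' deposited table. Of 11 heat shock genes 0, 4, 4 and 0 were higher (0, 7, 6 and 0 adjusted over the list alone, and 0, 1, 0 and 0 with centring), with Hsph1 at 1.07 at 4 h in the authors' deposited table. Of 20 fibroblast and feeder cell genes 0, 2, 5 and 2 were higher and 1, 1, 0 and 0 lower (the same counts adjusted over the list alone, and 0, 1, 1 and 2 higher with centring), with Fbn1 at 1.67 at 8 h in the authors' deposited table. The proliferation, p53 response, heat shock and fibroblast lists did not pass cameraPR with all genes at any auxin time. Their lowest adjusted p by cameraPR was 0.27, for fibroblast and feeder cell genes at 4 h. No call was made among 5 measured histone genes, and only 4 genes of the cleavage-stage list were measured, too few for a test.

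The median fold change was above 0 at every auxin time. One scaling factor from the spike-in calibration is a candidate explanation: among entries with 500 or more untreated reads the medians of 4 length quartiles lay within 0.062 of each other at 8 h, under the bound of 0.1 set beforehand. The bootstrap interval of that spread was 0.049 to 0.078, and the medians fell from 0.53 for the shortest to 0.47 for the longest. They also fell with length at the earlier times, from 0.21 to 0.12 at 2 h and from 0.43 to 0.41 at 4 h. The fall at 2 h was larger than that at 8 h, although the median of entries with 50 or more untreated reads was only 0.15 at 2 h. The spread at 2 and 4 h was not tested. At 24 h they spread over 0.214, from 0.34 for the shortest to 0.12 for the longest, which argues against one factor as the whole shift at that time. A rise of most transcripts on loss of PRC1 could give the same medians, and with 0 auxin-treated libraries without the degron it cannot be told apart.

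The stress response list was lower relative to other genes, although its members went both ways. The list median lay -0.40 from that of entries with 50 or more untreated reads at 24 h, with a bootstrap interval of -0.48 to -0.087, and the highest adjusted p of cameraPR over the settings run was 0.0094. One scaling factor moves every gene alike, so it cancels by construction from a difference relative to other genes. These values therefore restate the difference and are no separate test of that factor. The interval also reaches above a bound of -0.1 used first. Auxin or the change of medium may contribute, and the signs in the PRC2deg line cannot decide whether either does. Of 24 members, 66.7% were negative there, with a binomial interval of 44.7% to 84.4% that holds the bound of 75%. That interval takes genes as independent. Among all PRC2deg entries with 50 or more untreated reads, only 45.1% lay above 0, so a lean to negative was not particular to this list. Auxin itself was not given to the PRC2deg line. An effect of PRC1 loss was not tested apart from that of auxin.

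Entries higher at 2 h of auxin were positive in the PRC2deg table in 60.2% of cases, against 48.9% to 54.6% for entries matched on reads and length, which argues against a trend of sign with expression level or length as the whole cause. The share was 11.5 percentage points higher in the quartile with the largest PRC1deg change than in the quartile with the smallest, and 10.9 beyond matched entries. From the smallest change to the largest, the quartiles held 52.1%, 61.3%, 63.8% and 63.6%, so the share was lowest in the first and did not rise steadily. With each of 970 symbols counted once, the share was 59.8%. All signs come from a single comparison of the same libraries. The matched ranges treat entries as independent and leave out variation between libraries that genes share. Within that limit, a small rise at 2 h of SUZ12 loss of the genes higher at 2 h of auxin is a hypothesis that these shares fit but do not establish. Whether PRC1 represses each of those genes was not tested apart from auxin. Single lists mostly do not bear on it: among list members higher at 2 h of auxin, 72.7% of 22 Hox cluster genes were positive, above the 31.8% to 68.2% of matched genes, while 75% of 20 axon guidance and ion channel genes (40.0% to 85.0%), 66.7% of 12 mesoderm genes (16.7% to 66.7%), 64.5% of 31 Pax, Sox, Fox, Tbx, Gata and Zic factors (32.3% to 67.7%), 59.1% of 22 Wnt, Fgf, Bmp, Notch and Hedgehog genes (27.3% to 68.2%), 48.3% of 60 other homeobox genes (40.0% to 65.0%), 16.7% of 6 trophoblast genes (0% to 83.3%) and 14.3% of 7 endoderm genes (14.3% to 85.7%) lay within theirs. No entry was called, and these fold changes were shrunken nearly to 0.

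A hypothesis that long genes lag, since RNA polymerase needs longer to cross them, was tested on the 4430 entries higher at 8 h. The 2 h share of the 8 h change had a Spearman rho of 0.038 with length within bins of untreated reads, across entries that are not independent replicates, where the hypothesis needed a value below -0.1. Only 1839 of these entries passed at 8 h with centring. For the others the share largely mixes in the median shifts of 0.15 at 2 h and 0.50 at 8 h. The rho therefore does not decide whether induced long genes lag. Among entries also higher at 2 h, the median share was 73.4% in the shortest quartile and 61.8% in the longest, a split made after that result was seen and not tested.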
